A study of Drosophila melanogaster with 2 samples.

How the data were processed

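The samples were 2 biological replicates of 1 group, whole Drosophila melanogaster embryos aged 0 to 16 hours that carried a transgene for CG31441 joined to eGFP. Per the labels, chromatin was fragmented by sonication and precipitated with an antibody against GFP (ChIP-seq). The group and the replicate numbers were taken from the labels. Control libraries were not analysed here.

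The analysis started from 8 deposited peak lists on assembly dm6, in the narrowPeak layout. Per the readme deposited with each sample, the 4 lists of the whole series were made from the filtered alignments of both replicates and 1 further input file, and the 4 lists of single replicates from the alignments of that replicate and 1 further file. The same further file is an input of a track that the readme names as fold change over control. Each thresholded list has 1 more input whose role the readme leaves open. The aligner, the peak caller and their versions are not given in the sources used here. Peaks were therefore called by the authors both per replicate and on the replicates together. The signal of a peak is the authors' deposited value from their peak caller, and its scale is not stated. The −log10 values are q-values as deposited by the authors in the narrowPeak layout, and no result rests on them. The score is the authors' deposited scaled irreproducible discovery rate (IDR), a measure of how well the rank of a peak repeats between lists. In 100% of ranked peaks it lay within 1 of a fixed multiple of the −log2 global IDR, capped at the highest value of 1000. The summit was taken from the deposited offset within each peak. The 2 ranked lists of the series also hold 16 columns of values for single inputs that no label ties to a replicate, and these were not used.

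The conservative list of the series was the main peak set. It held 6501 peaks, and the highest global IDR among them was 0.00999837. In the ranked list of true replicates, 6627 peaks had a global IDR of at most 0.01, so that threshold alone does not give the list. The less strict list held 7408 peaks, and 353 conservative peaks overlapped none of these. In the conservative list 868 peaks shared their interval with another peak that had its own summit, so peaks were also counted as 5614 merged regions. Signal was under 20 at 189 peaks. Read counts and library depth are unknown, so no interval or detection limit that needs depth is given. Confidence intervals are on counts of genes or peaks and cover counting error only.

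Coordinates are 1-based on dm6. Sequence and soft-masking came from the RefSeq genome of the same assembly, and genes from the Ensembl release 115 annotation (BDGP 6.54), with 13968 protein-coding genes and 19630 TSSs. Summits were assigned in order of priority to promoter (within 500 bp of a TSS), 5' untranslated region, coding exon, 3' untranslated region, intron and other. Mitochondrial peaks were left out of all such shares. A summit was called masked if its own base was soft-masked, whatever the bases around it. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

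Observed shares were compared with 1000 sets of random positions, drawn on the same chromosome arms, by two-sided permutation tests. With 1000 sets the smallest p is 0.002. The overlap of the replicates was compared with shuffles of 1 list within arms, 1000 of them, or 100 for reciprocal overlap. Median log2 signal was compared between promoter and other peaks with 100000 resamples. For 17 gene lists, the share of members with a promoter summit was compared with all other protein-coding genes by two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the lists, with a threshold of 0.05 and at least 8 members per list. For 16 sequence motifs, matches within 50 bp of the summit were compared with a window centred 400 bp away on a randomly chosen side of the same peak, by exact McNemar tests. Words of 8 bases were searched on chromosomes 2 and 4 and tested on chromosomes 3 and X, with both flanks as control. Peaks, genes and words are not independent replicates, so these p-values describe the lists and not the spread between embryos.

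The statistics were tested on simulated data first. For the promoter share, of 6476 random positions 20% were moved to TSSs and 19.7% were recovered. With signal doubled at promoters among 6476 peaks, the log2 difference came out as 1.00. With no effect planted among 6476 windows, 0 words and 0 motifs were called, and 2 of 2 planted words and 1 of 1 planted motif were found. These windows lay at random positions, which lack the lower G and C content that real summits had against their flanks. The simulation therefore does not show how often base composition alone leads to calls against the flanks. Fisher's exact test of gene lists was too liberal. With random genes bound, about as many as in the data, at least 1 list was called in 58 of 200 draws (76 of 3400 tests). Members of some lists share promoters or lie side by side, which that test ignores. A second test was therefore added after the data were seen. It compares the odds ratio of each list with 1000 placements of as many summits at promoters of random genes. It called a list in 12 of 200 such draws (13 of 3400 tests). The draws were made in the same way as the placements, so this low rate was set in advance. The placements keep shared promoters together but pick genes independently. Peaks that occur in groups over neighbouring genes are therefore not covered. Both tests found the cytosolic ribosomal list, with 60% of its genes bound, in 200 of 200 draws. Detection in smaller lists or with weaker effects was not simulated. Both p-values are given where they part.

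The tests, the gene lists, the motifs and the rule for naming genes were fixed before the data were examined. The rule takes the tagged gene, the 25 strongest conservative peaks whose summit lay in a thresholded peak of both replicates, up to 4 members with the strongest promoter peak per list, the 3 strongest peaks of each replicate absent from the other's thresholded list, the 5 words with the lowest p and the 5 windows of 100 kb with the most peaks. A peak is named by the gene with a TSS within 1000 bp, otherwise by the gene it lies in or the nearest gene. A gene that this rule takes is not reported here. A few symbols of the fixed lists had no exact match in the annotation and were not counted. The name pattern of the chorion list also takes Cp190 and Sgs genes, and that of the receptor list also takes ionotropic receptors. The alternatives set beforehand were the less strict list, the list of each replicate alone, a global IDR of at most 0.01, the stronger 50% of peaks, major arms without masked summits, other windows and distances, 1 TSS per gene, shared promoters counted once, promoters without a peak as motif control, swapped discovery and test arms, and words of 6 bases. Those added after the data were seen were merged peaks, a global IDR of at most 0.001, summits with at least 35% G and C, positions and windows matched on G and C, both of these together for words and motifs, Cp190 left out of the chorion list, and the random promoter placements.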

Results

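The series mapped where CG31441, a predicted zinc-finger protein, was found on the genome of Drosophila melanogaster embryos. Flies carried a transgene that joins CG31441 to enhanced green fluorescent protein (eGFP), and chromatin of whole embryos aged 0 to 16 hours was sonicated and precipitated with an antibody against GFP. The labels describe 2 biological replicates of 1 condition, so the comparisons open to these data are between the replicates, between peak positions and random positions, and between named groups of genes or sequences. The libraries were ChIP-seq, and the deposited values are lists of peaks on assembly dm6. The conservative list of the whole series held 6501 peaks in 5614 regions without overlap, with a median width of 395 bp, covering 2.31 Mb. The thresholded list of replicate 1 held 4964 peaks and that of replicate 2 held 5484. Read counts were not in the files used, so the depth of each library is unknown. Peak signal is the authors' value for each peak. Its scale is not stated and can differ between lists, so a ratio of signals from 2 lists describes the lists and is no measure of binding. No test across the 2 replicates was made for single peaks, since the design has 1 group and the lists can differ in scale.

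The tagged gene had a thresholded peak near it in the conservative list alone, and further peaks in the ranked lists. CG31441 (FBgn0051441) lies on 3R from 11236286 to 11237624 on the plus strand. The conservative list held 1 peak within 2 kb of it, with a signal of 142.0 and a summit 1093 bp from the transcription start site (TSS), and 0 peaks in the gene body. The less strict list and the thresholded lists of both replicates held 0 peaks within 2 kb. Before thresholding, the ranked list of replicate 1 held 2 peaks there, with a highest signal of 78.9 against a list median of 33.2, and that of replicate 2 held 4, with a highest signal of 57.0 against a median of 20.5. Their nearest summits lay 130 and 71 bp from the TSS. The ranked list of true replicates held 4 peaks within 2 kb, with a highest signal of 142.0 as in the conservative list, and 2 of them were in the gene, with a highest signal of 118.9 there, and the other ranked list of the series held 1, with a signal of 48.1. A transgene copy of the locus can add reads of its own, so this value is only a partial check of the labels.

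The replicates shared most of their peaks. Of the 4964 thresholded peaks of replicate 1, 3958 (79.7%) overlapped a thresholded peak of replicate 2 by at least 1 bp, against 3.29% ± 0.25 (SD of 1000 shuffles within chromosome arms; two-sided permutation p = 0.002, the smallest that 1000 shuffles can give). In the other direction, 68.5% of the 5484 peaks of replicate 2 overlapped one of replicate 1. In the ranked, unthresholded list of replicate 2, 98.1% of the replicate 1 peaks had a partner, against 16.0% ± 0.54 (SD) for shuffled peaks. Across 17945 peaks present in both ranked lists, Spearman's rho of signal was 0.708 and Pearson's r of log10 signal was 0.716 (permutation p = 0.002 for rho, the smallest possible). This is a correlation across peaks, which are not independent replicates. At 3552 conservative peaks whose summit lay in a thresholded peak of both replicates, the signal of replicate 1 was a median 1.32 times that of replicate 2, with 0.964 at the 10th percentile and 2.01 at the 90th. Of the 6501 conservative peaks, 4023 overlapped a thresholded peak of both replicates and 930 overlapped a thresholded peak of neither.

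CG31441-eGFP peaks lay at promoters far more often than random positions did, and almost never in coding exons outside the promoter window. Of 6476 nuclear summits, 2361 (36.5%) lay within 500 bp of the TSS of a protein-coding gene, against 11.4% ± 0.40 (SD) for random positions on the same arms, a ratio of 3.19. Coding exons outside the promoter window held 14 summits (0.216%), against 13.9% of random positions. Coding sequence inside that window was not counted apart. The 3' untranslated regions held 54 summits (0.834% against 4.52%) and the 5' untranslated regions outside the promoter window held 26 (0.401% against 0.792%). Sequence outside genes and promoters held 1441 summits (22.3% against 30.2%). Each of these 5 classes differed from 1000 random sets (two-sided permutation p = 0.002, the smallest possible; Benjamini-Hochberg adjusted p = 0.0024 over the 6 classes). Introns held 2580 summits, 39.8% against 39.2%, a difference within the spread of random sets (permutation p = 0.33). Against random positions matched on arm and on the G and C content of the 50 bp on each side, the promoter share expected was 11.6%. No other class was compared with such matched positions, so how far base composition bears on the coding exon share was not tested.

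**Figure D1:**
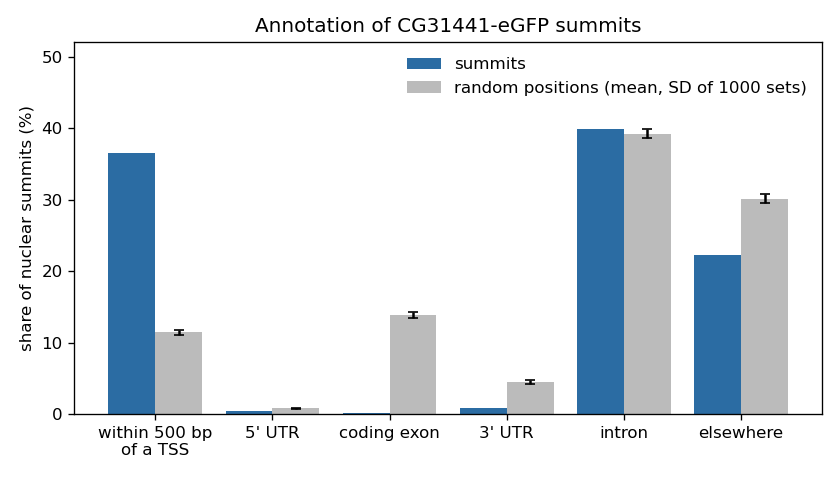
Share of the 6476 nuclear summits of the conservative list in each annotation class (blue bars, percent), beside the mean share of 1000 sets of random positions on the same arms (grey bars, with the SD over sets as error bars). Promoters held 36.5% of summits against 11.4% of random positions, and coding exons outside the promoter window held 0.216% against 13.9%.

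Within promoters, the summits lay just upstream of the TSS. Of the 2361 promoter summits, 1953 (82.7%) were upstream of the nearest TSS, and the median distance to it was 150 bp. The interval from 50 to 250 bp upstream held 50.7% of them, while the same interval downstream held 8.22%. A promoter summit was present at 2541 of 13968 protein-coding genes (18.2%), where a summit between 2 divergent genes counts for both.

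**Figure D2:**
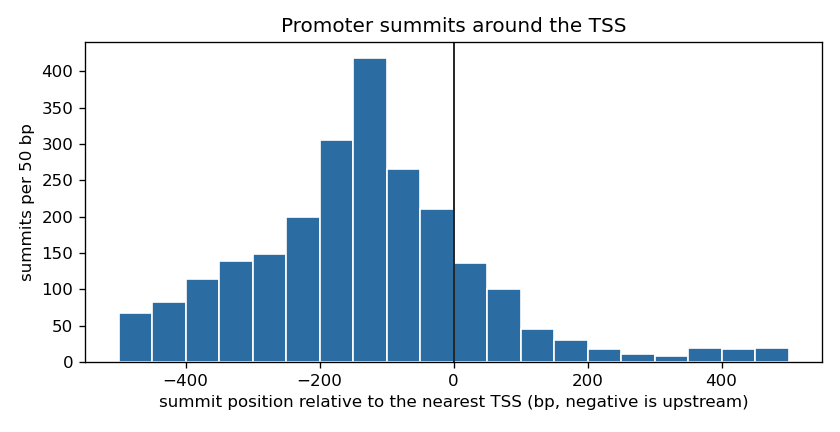
Number of promoter summits per 50 bp (vertical axis) by position relative to the nearest protein-coding TSS (horizontal axis in bp, negative values upstream) for the 2361 promoter summits of the conservative list. The highest bar, 419 summits, spans 150 to 100 bp upstream of the TSS.

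The strongest peaks were promoter peaks in larger part. Among the 500 strongest nuclear peaks, 62.4% were at promoters, and the share was 44.2% in the next 500, 39.6% in the 1000 after these, 30.8% in the 2000 after those and 33.0% in the weakest 2476. The median signal was 200.8 at 2361 promoter peaks and 173.6 at 4115 other peaks, a log2 difference of 0.21 (two-sided permutation p = 2e-05 across peaks, the smallest that 100000 resamples can give). The call was lost without replicate 1, in the list of replicate 2 alone, where the log2 difference was 0.03 (permutation p = 0.28).

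The strongest peaks found in both replicates lay at genes of several kinds. The highest signal of the list, 950.5, was on 3R from 15208419 to 15209607, with the summit 93 bp from the TSS of Mau2, a subunit of the cohesin loader, and within 500 bp of Spn88Eb. In the replicates' own lists this peak had signals of 514.9 and 447.0 (mean 481.0 ± 48.0, SD, n = 2). Next came oxt with CG13807, the former a peptide O-xylosyltransferase gene (914.2, on 3L from 2262330 to 2263189), the gene CG18476 (889.4, on 3R from 11677841 to 11678749) and Rme-8, an endocytosis gene (885.3, on 2R from 9176914 to 9177952). Among the genes that encode chromatin regulators, the promoter of Sfmbt, a Polycomb group gene, had a signal of 849.6, in a peak also at the TSSs of CG43925 and CG5439, and that of brm, the ATPase of the Brahma remodelling complex, had 830.0, in a peak also at the TSS of Arl1. A peak 4211 bp from Psc, another Polycomb group gene, had 772.9. A peak in an intron of Trl, which encodes the GAGA factor, had 743.8. Introns of Dif, an NF-kappaB family gene of the immune response, of CG11050 and of CG32772 carried 717.7, 707.4 and 683.8, and an intronic peak 798 bp from the TSS of the calcium channel gene Orai carried 815.6. The other promoters among the 25 strongest were those of CG6833 (817.0), CG11247 with Polr2H (791.6), Hydr1 with CG18659 (771.1), CG14100 (752.2), cu (706.4), CG13390 with CG17294 (702.6), mRpL41 (702.3), CG31145 (695.6), Art3 with mRpS10 (693.6), CG10628 with Dus3 (687.4) and Lon with PIG-F (680.7). In all, 17 of the 25 were at promoters, 5 in introns, 1 in other sequence and 2 on mitochondrial DNA, at mt:ND4 (752.8) and mt:srRNA (735.5). In 21 of the 25 the signal was higher in the list of replicate 1.

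Some peaks were in the thresholded list of 1 replicate alone. Replicate 1 had 1006 such peaks, of which 910 had an overlapping peak in the ranked list of replicate 2. The strongest lay at the promoters of MRP, an ABC transporter gene (signal 323.6, on 2L from 12721834 to 12722318), Meics, a meiotic spindle gene (274.2, on 3L from 13964610 to 13965290), and SF1, a splicing factor gene (225.1, on 3R from 17540230 to 17540497). The MRP peak overlapped no ranked peak of replicate 2, while those of Meics and SF1 did. Replicate 2 had 1726 such peaks, of which 1358 had an overlapping peak in the ranked list of replicate 1. Its strongest were at the promoters of Gk1, a glycerol kinase gene (258.1, on 3L from 205782 to 206126), POSH (255.8, on 2R from 17568474 to 17568807) and PolD2, a DNA polymerase delta subunit gene (238.4, on 3L from 1775317 to 1775680), and none of these 3 overlapped a ranked peak of replicate 1. The median signal of such peaks was 102.1 against 129.8 for the whole list of replicate 1, and 67.7 against 88.2 for replicate 2.

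Genes that encode cytosolic ribosomal proteins carried promoter peaks more often than other genes. Of 86 such genes, 61 (70.9%, exact 95% confidence interval 60.1 to 80.2%) had a summit within 500 bp of a TSS, against 17.9% of all other protein-coding genes (odds ratio 11.2; Fisher's exact test, two-sided, adjusted p = 1.65e-25 over 17 lists). Among the strongest members were RpS27 (signal 530.7, on 3R from 25247308 to 25247911), RpL7 (472.8) and RpL34b (442.2). Genes on the broad list of insulator and promoter architecture factors, which also takes Top2 and cohesin genes, were bound at 12 of 23 (52.2%, odds ratio 4.92, adjusted exact p = 0.000667). Cp190 had the strongest of these promoter peaks (602.2, on 3R from 15275131 to 15275631), followed by Chro (585.0), Top2 (579.9) and mod(mdg4) (293.1). Against 1000 placements of as many summits at promoters of random genes, a null that keeps shared promoters together, the calls held for the cytosolic ribosomal list (adjusted permutation p = 0.00679, from the smallest p that the placements can give) and the architecture list (adjusted permutation p = 0.0113). This null was added after the data were seen, because Fisher's test called lists too often in simulated data. Mitochondrial ribosomal protein genes were bound at 24 of 73 (32.9%, odds ratio 2.21, adjusted p = 0.00528 by Fisher's exact test), but this call was lost against random placements (adjusted permutation p = 0.0722). It was also lost with masked summits left out (adjusted exact p = 0.29), and the odds ratio was 0.577 among summits with at least 35% G and C. The call held in the other settings, among them shared promoters counted once (odds ratio 3.02, adjusted exact p = 6.48e-05). Their strongest members were mRpL41 (702.3), mRpS10 (693.6, a peak it shares with Art3), mRpS23 (624.7) and mRpS2 (606.9). Genes of a list that share a promoter or lie side by side are not independent.

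**Figure D3:**
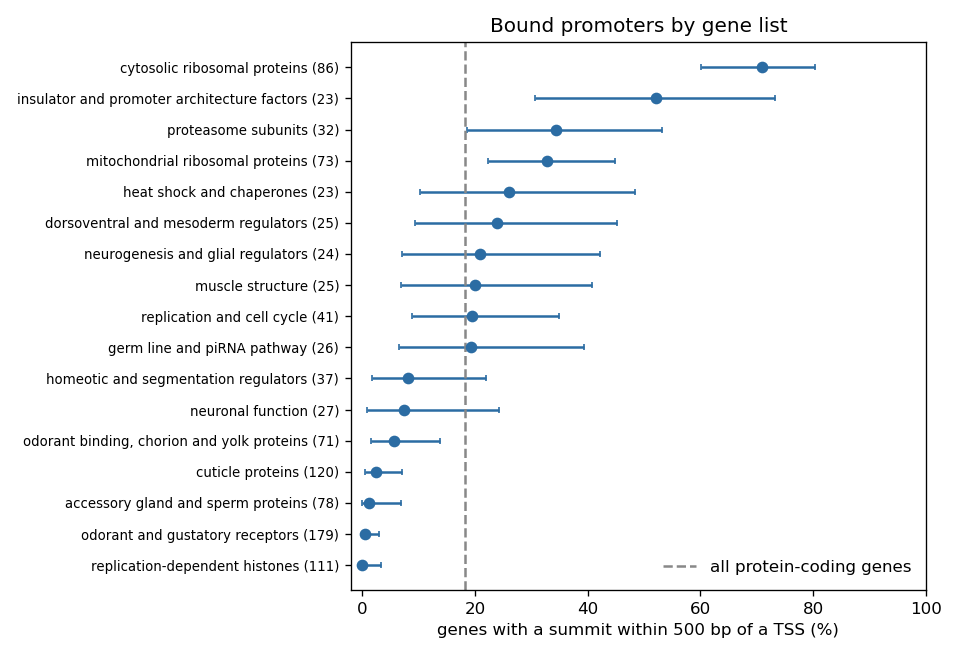
Percent of genes with a summit of the conservative list within 500 bp of a TSS (horizontal axis) for the 17 fixed gene lists, with the number of genes in each list in parentheses. Points are shares, bars are exact 95% binomial confidence intervals, and the dashed line is the share of all protein-coding genes, 18.2%. Cytosolic ribosomal protein genes lay at 70.9% and replication-dependent histone genes at 0%.

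Genes of 5 lists carried fewer promoter peaks than other genes. Odorant and gustatory receptor genes, a list whose pattern also takes ionotropic receptors, were bound at 1 of 179 (Or88a, signal 76.1; odds ratio 0.0249, adjusted exact p = 1.44e-13). Accessory gland and sperm protein genes were bound at 1 of 78 (Sfp26Ad, signal 168.8; odds ratio 0.0580, adjusted exact p = 1.66e-05). Cuticle protein genes were bound at 3 of 120 (odds ratio 0.114, adjusted exact p = 6.88e-07), namely Cpr67Fa1 (121.5), Cpr65Ea (116.3) and Cpr65Av (97.5). Odorant binding, chorion and yolk protein genes were bound at 4 of 71 (odds ratio 0.267, adjusted exact p = 0.00674). One member of that list, Cp190, is an insulator protein that the fixed name pattern also took, and without it 3 of 70 were bound, Obp99b, Obp83g and Sgs3 (odds ratio 0.2004, adjusted exact p = 0.00228). Sgs3 is a member because the pattern also takes Sgs genes, which the name of the list leaves out. The list's call was lost with masked summits left out (adjusted exact p = 0.133) and among summits with at least 35% G and C (adjusted p = 0.485), where the accessory gland and sperm list also lost its call (adjusted p = 0.122). Replication-dependent histone genes were bound at 0 of 111 (upper 95% bound 3.27%, adjusted exact p = 2.32e-09). These lie in a tandem repeat, where reads may not map to a single place, so a missing peak there does not show missing protein. The p-values of these 5 lists are from two-sided Fisher's exact tests, and against random placements the 5 had adjusted permutation p from 0.00679 to 0.0146. Some of the named peaks were not in both replicates' thresholded lists. The summit at Or88a lay in a thresholded peak of replicate 1 alone. Those at Cpr67Fa1, Cpr65Ea, Obp83g and Sgs3 lay in one of replicate 2 alone, and that at Cpr65Av in one of neither.

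The other 9 lists did not pass the test. Proteasome subunit genes were bound at 11 of 32 (34.4%, odds ratio 2.36, adjusted p = 0.0654 by Fisher's exact test), with the strongest peaks at Rpn3 (355.9), Prosbeta2 (349.7), Rpn5 (296.7) and Rpt2 (272.3). The proteasome genes passed in the less strict list (adjusted exact p = 0.00701), in the list of replicate 1 alone (0.0323), with merged peaks (0.0398), with a window of 250 bp (0.00581) and with shared promoters counted once (0.0285). They failed against random placements (adjusted permutation p = 0.166). Heat shock and chaperone genes were bound at 6 of 23, with Hsp27 (599.0), Hsc70-5 (464.5), Hsp83 (395.8) and Hsp26 (362.0) the strongest, and the adjusted p was 0.41, but 0.00920 in the list of replicate 2 alone (odds ratio 3.41). The lists of patterning, tissue and cell cycle genes did not pass either. Among homeotic and segmentation regulators 3 of 37 had a promoter peak, at nkd (521.7), bcd (177.9) and ptc (159.4). Among dorsoventral and mesoderm regulators 6 of 25 did, with tin (497.6), cact (346.4), htl (303.9) and Tl (108.3) the strongest. Neurogenesis and glial regulators were bound at 5 of 24, led by elav (575.4), E(spl)mdelta-HLH (357.2), grh (241.9) and N (230.3). Neuronal function genes were bound at 2 of 27, Nrx-1 (313.9) and comt (261.2). Muscle structure genes were bound at 5 of 25, led by Msp300 (405.9), Act87E (369.9), sls (345.3) and Tm1 (342.5). Germ line and piRNA pathway genes were bound at 5 of 26, led by orb (457.5), gcl (304.5), bgcn (298.7) and pum (209.9). Replication and cell cycle genes were bound at 8 of 41, led by CycE (557.8), aurA (434.0), RnrS (421.8) and aurB (368.7). The adjusted p of these 7 lists ranged from 0.230 to 0.839. Not all peaks named for the 9 lists were in both replicates' thresholded lists. The summits at Prosbeta2, Rpn5, htl, Tl and gcl lay in a thresholded peak of replicate 1 alone. Those at grh and bgcn lay in one of replicate 2 alone. Of 290 tRNA genes, 22 (7.59%) had a summit within 500 bp, against 17 of 301 small nuclear and small nucleolar RNA genes (5.65%; two-sided Fisher's exact p = 0.41) and 4.23% at random positions (two-sided permutation p = 0.012).

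Peaks were spread over the large arms and occurred in groups. There were 51.8 peaks per Mb on 2L, 42.6 on 2R, 54.4 on 3L, 44.1 on 3R and 51.9 on X, against 11.9 on chromosome 4, and Y held 0 peaks. The density on X was 1.08 times that on the large autosomal arms (two-sided permutation p = 0.016 against random positions and p = 0.004 against random TSSs). That call was lost without replicate 1 (ratio 1.04, permutation p = 0.29) and without replicate 2 (ratio 1.05, permutation p = 0.21), and among the stronger 50% of peaks, where the ratio was 1.083 over fewer peaks (permutation p = 0.09). The p-values for X come from random counts that place each summit independently. Since the summits occurred in groups, they may be too small. They also take no account of the spread between arms, and X lay within the range of the large autosomal arms. Of the nuclear summits, 69.5% had another summit within 5 kb, against 38.7% ± 0.75 (SD) for random positions and 60.02% ± 0.64 for random TSSs (two-sided permutation p = 0.002 for each, the smallest possible). With overlapping peaks merged, the share was 58.2% against 55.4% for random TSSs. The 5 windows of 100 kb with the most peaks were all on 3L, and the median window of the major arms held 4 peaks. The window from 11400001 to 11500000, with its strongest peak at CG44362, held 32 peaks, of which 1 was at a promoter, and the window before it, from 11300001, held 30 with its strongest at CG6168. The window from 700001 to 800000 held 28, strongest at CG13896 and including emc, a helix-loop-helix regulator gene. The window from 10800001 to 10900000 around tna held 23, and that from 18200001 to 18300000 around CG5103 held 22.

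The summits were AT-rich. The mean G and C content within 50 bp of 6476 nuclear summits was 31.5%, against 43.8% in windows centred 400 bp away, a difference of -12.3 ± 0.16 percentage points (SE across summits). Random nuclear positions averaged 42.3% (SD 10.3, n = 20000). The summit was below its flanks at 82.8% of peaks. The difference was -13.8 percentage points in the list of replicate 1 and -11.9 in that of replicate 2. It was -11.9 at promoter summits and -12.5 elsewhere. Stronger peaks were more AT-rich, with a mean of 27.4% in the 500 strongest and 35.2% in the weakest 2476. Repeat-masked sequence held 27.1% of summits against 20.1% of random positions (two-sided permutation p = 0.002, the smallest possible), and masked summits had a lower mean G and C content than the unmasked ones, at 33.5%. The share was 10.4% among summits with at least 35% G and C, a selection that by itself takes out masked summits, while the random positions were not selected. These 1888 summits made up 29.2% of the nuclear peaks. Of them 43.5% were at promoters, against 33.5% of the other 4588, and their median signal was 138.7 against 202.4.

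**Figure D4:**
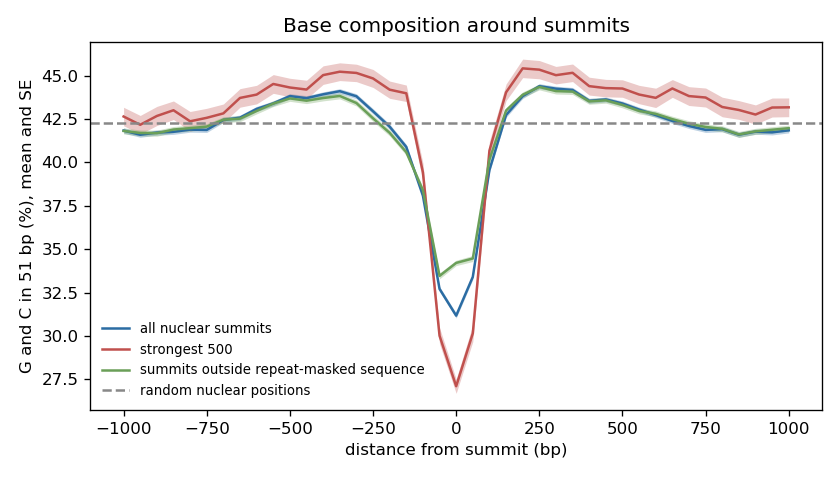
Mean G and C content of 51 bp windows (vertical axis, percent, not starting at 0) by distance from the summit (horizontal axis, bp) for all 6476 nuclear summits, the strongest 500 and the summits outside repeat-masked sequence, with SE across summits as shaded bands. The dashed line is the mean of random nuclear positions, 42.3%. At the summit the mean was 31.2% for all nuclear summits and 27.1% for the strongest 500.

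Of 16 known sequence motifs, 5 were more frequent at summits than in the flank of the same peaks and 6 were less frequent (exact McNemar tests, two-sided, Benjamini-Hochberg adjusted over the motifs). The DNA replication-related element, bound by Dref and BEAF-32, was at 1.204% of summits against 0.355% of flanks (adjusted exact p = 4.99e-08). Core promoter motif 1, bound by M1BP, was at 1.02% against 0.355% (adjusted exact p = 1.01e-05), a call lost without replicate 2 (adjusted p = 0.0595). Core promoter motif 6 was at 5.36% against 2.19% (adjusted exact p = 1.67e-20), the TATA box at 7.63% against 3.35% (adjusted p = 1.31e-26), and the CTCF motif at 0.695% against 0.371% (adjusted p = 0.0224), a call also lost without replicate 2 (adjusted p = 0.93). The less frequent motifs were the Zw5 motif at 4.35% against 9.64%, the Pho motif at 11.8% against 19.1%, the E-box at 2.75% against 5.19%, the GAGA motif at 1.30% against 2.76%, the CA repeat at 0.417% against 2.13% and the Initiator at 8.29% against 9.59%, with adjusted p from 8.50e-32 to 0.0169. The Initiator call was lost without replicate 1 (adjusted exact p = 0.71) and in most of the other settings. The motif 1 and CTCF calls were also lost among the stronger 50% of peaks (adjusted exact p = 0.113 and 0.50). The Zelda motif (0.494% against 0.757%, adjusted exact p = 0.092), the Su(Hw) motif (0.371% against 0.170%, adjusted p = 0.0546), core promoter motif 7 (1.95% against 1.54%, adjusted p = 0.105), the ZIPIC motif (0.649% against 0.602%, adjusted p = 0.82) and the Grainyhead motif (0.124% against 0.154%, adjusted p = 0.82) did not pass. In the list of each replicate alone, Zelda was lower (adjusted exact p = 0.0244 in replicate 2 and 0.00420 in replicate 1) and Su(Hw) higher (0.0167 and 0.00225).

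Several of these calls changed with another control. Against random windows matched on arm, promoter class and G and C count, a control chosen after the data were seen that differs from the flanks in more than base composition, 7 motifs were more frequent at summits and 0 less frequent. They were the CTCF motif (0.695% against 0.108%, adjusted p = 2.70e-10), the replication-related element (1.205% against 0.556%, adjusted p = 1.21e-05), core promoter motifs 1 and 7, the ZIPIC motif, the GAGA motif (1.30% against 0.749%, adjusted p = 0.000674) and the E-box (2.75% against 2.17%, adjusted p = 0.0320), all by two-sided Fisher's exact tests. The calls of the replication-related element, motif 1 and the CTCF motif thus held, the E-box and the GAGA motif changed direction, and motif 6 and the TATA box lost their calls (adjusted exact p = 0.50 for each). Against the same offsets at promoters without a peak, promoter summits had more motif 6 (5.93% against 3.85%, adjusted exact p = 0.00619) and TATA box (7.88% against 5.84%, adjusted p = 0.0216), and fewer Zw5, Pho and Initiator matches. These control promoters were not matched on G and C, so base composition may bear on these differences. With matched windows the Zw5 (adjusted exact p = 0.60), Pho and Initiator motifs (0.50 for each) did not differ past the threshold. The replication-related element (adjusted exact p = 0.26), motif 1 (0.74) and the CTCF motif (0.73) did not differ past the threshold there.

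A search over 32896 words of 8 bases found many words of A and T alone. Against the flanks, 301 words passed on chromosomes 2 and 4, of which 293 passed again on chromosomes 3 and X (exact binomial, one-sided, Bonferroni adjusted), and 126 of these held A and T alone. The 5 with the lowest p in the discovery arms were TATTTTAA, TTTAAAAA, AAATATAT, ATTTAAAA and TAAAATAA. On the test arms TATTTTAA was at 6.99% of summits against 1.66% of flanks and AAATATAT at 8.04% against 2.27%. With windows matched on base composition, 1 word passed on both sets of arms, CACTGTGC, at 0.792% of the test summits against 0.240% of matched windows (Bonferroni adjusted exact p = 1.53e-05). Among summits with at least 35% G and C, 0 words passed against the flanks.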

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

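Of the tests in this part, the comparison of AT-rich promoters between gene lists and the comparison of ribosomal protein genes with other genes used in all cells were chosen after the results were seen, and the other tests were set down before. The design has 1 group, so no biological explanation was tested between groups.

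Peaks appeared in sequence outside the comparisons. The conservative list held 25 peaks on mitochondrial DNA, in 9 merged regions that covered 57.0% of its 19524 bp, with a median signal of 201.7 against 180.4 at nuclear peaks and a highest signal of 752.8, at mt:ND4. The ranked list of true replicates held 1 peak on an unplaced scaffold. For the mitochondrial peaks, a candidate technical source is AT-rich base composition, since mitochondrial DNA holds 17.8% G and C. Among sequence with 13 to 23 G or C per summit window, mitochondrial DNA had 7 summits at 1073 per Mb and nuclear DNA 1254 at 320.1 per Mb, a ratio of 3.35 (95% interval 1.34 to 6.92). The interval spans both a density near that of AT-rich nuclear sequence and one well above it, so base composition cannot be told apart from other sources, because only 7 of the 25 summits lay in the range compared. The many copies of mitochondrial DNA per cell, and how the further input file was used there, stay open as well.

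The AT-rich summits are a pattern that recovery or amplification of AT-rich fragments could make. If such DNA were recovered alike wherever it lies, promoters with an AT-rich stretch would carry peaks as often in the 3 lists of genes little used in embryos as elsewhere. Such a stretch was near a TSS of 73.8% of the genes in those lists and 79.3% of the others, and the lists were known to carry few peaks when this test was chosen. Among genes with such a stretch, 5 of 242 in those lists and 2321 of 10823 others had a promoter peak, an odds ratio of 12.9 (95% interval 5.46 to 40.3), which argues against AT content alone. A masked base at the summit is also not the whole cause, since summits with an unmasked base were still -10.2 percentage points from their flanks (95% interval -10.5 to -9.80). The rest of the summit window could still be masked, so masked sequence beside the summit was not excluded. A bias that acts only on open chromatin, and a preference of the protein for AT-rich DNA, both stay open.

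Peaks at cytosolic ribosomal protein promoters stood out among the gene lists, and AT-rich promoters were weighed as their source. The lowest count of G and C in a summit-sized window near the TSS had a median of 22 in this list and 23 in other genes. Stratified over 10 classes of that count, the odds ratio was 10.3 (95% interval 6.38 to 16.8), so AT content does not account for the list. The cytosolic genes were bound more often, at 61 of 86, than mitochondrial ribosomal and proteasome genes, at 35 of 105 (odds ratio 4.84, 95% interval 2.52 to 9.50). The counts of these lists were known when the comparison was chosen. The lists compared do not stand for all genes used in all cells, so wide use as a source was not excluded. High transcription, or open chromatin that goes with it, was not measured and stays open, since ribosomal protein genes are among the most transcribed.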

How the results depend on the processing

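Merged peaks, a global IDR of at most 0.001, summits with at least 35% G and C, controls matched on G and C, Cp190 left out and random promoter placements were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because the design has 1 group. The planned global IDR of at most 0.01 removed no peak and tests nothing. The overlap and the correlation of the replicates cannot be computed without a replicate, and the masked share is fixed when masked summits are left out. The promoter share, clustering and the overlap and correlation of the replicates kept their direction and their side of the threshold under each alternative run for them. Depth is unknown, so how far it limits the weaker peaks could not be tested.

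The stronger 50% of peaks, which are fewer by construction, were 3251 peaks and gave 181 enriched words of 8 bases and 3 enriched motifs, and the X ratio of 1.083 was no longer past the threshold (permutation p = 0.09). With a global IDR of at most 0.001, 2631 peaks, 99 words and 3 enriched motifs were left, the X ratio was 1.086 (permutation p = 0.106), and the CTCF motif was at 0.345% of summits, below its flanks. Leaving out masked summits gave 77 words, and swapping the discovery and test arms gave 444. Without a replicate, the X ratio ranged from 1.04 to 1.05, past the threshold in neither, the log2 difference of promoter signal from 0.028 (not past the threshold, without replicate 1) to 0.21, and the number of peaks within 2 kb of CG31441 was 0 in each. That number was also 0 in the less strict list and in the gene body alone. The cause of the changes in the X ratio, the motifs, the words and the promoter signal was not tested.

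With summits of at least 35% G and C, 1888 peaks were left, the X ratio was 1.063 (permutation p = 0.31), 3 gene lists were depleted in place of 5, 0 motifs were depleted, and 0 words passed, or 1 with matched windows. The masked share was 10.4%, below that of random positions, but this selection takes out masked summits, which were lower in G and C, and the random positions were not selected, so the change of direction shows nothing on masking. The odds ratio of mitochondrial ribosomal protein genes was 0.577. In this subset the E-box was at 6.83% of summits, the GAGA motif at 3.39%, the Zw5 motif at 10.6% and the Pho motif at 19.0%, each above its flanks, and the TATA box at 3.28%, below them, none past the threshold against flanks. With windows matched on G and C for the same summits, 9 motifs were enriched, among them the E-box (adjusted exact p = 0.00149), the GAGA motif (4.82e-06) and motif 6 (0.00655), and 1 was depleted, the Initiator (9.06% against 11.3%, 0.0204). There the Zw5 motif and the CA repeat (1.43%) were above and the TATA box below its controls, none of the 3 past the threshold. Against windows matched on G and C for all nuclear summits, 0 motifs were depleted and 1 word passed. The E-box at 2.75% and the GAGA motif at 1.30% were above their controls past the threshold. The Zw5 motif at 4.36% was above its controls but not past it (adjusted exact p = 0.60). Matched windows take away the difference in base composition between summits and controls by construction. Summits with at least 35% G and C averaged 44.0% against 42.7% in their flanks, a difference that the choice of summits by this same window sets in part. With promoters without a peak as control, 2 motifs were enriched and 3 depleted. Over single genes, lists, words and motifs under their alternatives, 488 values or calls stayed the same, 155 values moved, 32 calls were lost, 23 were gained and 15 directions were reversed.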

Other observations

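The tests in this part, on Polycomb and trithorax group genes and on the word CACTGTG, were all chosen after the results were seen.

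Sfmbt, brm, Psc and Trl, genes of the Polycomb and trithorax groups, were among the genes named by the 25 strongest peaks, Sfmbt and brm by a promoter peak that also lay at the TSS of another gene, Trl by an intron peak and Psc as the nearest gene, with a TSS 4211 bp away. The hypothesis drawn from this, that genes of these groups carry more promoter peaks, was tested with these 4 and ph-d left out, 5 genes in all, because their peaks had been seen before the test. Of those left out, Sfmbt, brm, Trl (275.1) and ph-d (208.5) had a promoter peak and Psc had none. The share below thus leaves out genes with a promoter peak. Of the other 33 genes, 5 had a promoter peak (15.2% against 18.2% of other genes), an odds ratio of 0.804 (95% interval 0.242 to 2.11; two-sided Fisher's exact p = 0.82). The interval includes both a deficit and a doubling, so too few genes were at hand to decide. The 5 were E(z), the methyltransferase of a Polycomb complex, with a promoter signal of 545.6, Su(z)12 (236.6), skd (225.3), phol (128.8) and Su(z)2 (117.5). The last 2 were below the median nuclear peak of 180.4, with summits in a thresholded peak of neither replicate. These 5 are all of the tested genes with a promoter peak. Of the 28 tested genes without a promoter peak, 22 had 0 summits within the gene or 500 bp of it and 6 had at least 1, with a highest signal of 752.2 at ash1, 654.7 at osa, 404.5 at kis, 397.8 at ph-p, 312.3 at jing and 275.7 at trx, named after their values were seen. Peaks outside promoters were not tested for these groups, although Psc and Trl had such peaks. The signal at ash1 is that of the peak at the promoter of CG14100, which was among the 25 strongest, yet ash1 was not left out.

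Words with the core CACTGTG, or its complement CACAGTG, were the ones that passed when base composition was matched. CACTGTGC passed with matched windows over all summits, and CACAGTGG passed among summits with at least 35% G and C, at 2.45% of the test summits against 0.465% of matched windows. The hypothesis is that the protein, or a partner present with it, has a preference for this core beyond base composition. On chromosomes 3 and X the core was within 50 bp of 75 of 4165 summits (1.80%) and in 55 of 8330 matched windows (0.660%), an odds ratio of 2.76 (95% interval 1.92 to 3.99). It may instead be a promoter element found alike at promoters without a peak. Against the same offsets at such promoters, the core was at 29 of 1479 promoter summits (1.961%) and 76 of 7395 controls (1.03%), an odds ratio of 1.93 (95% interval 1.21 to 3.002), whose lower bound barely exceeds the 1.2 set for excluding that explanation. The control promoters were not matched on how far their genes are used in embryos. An element found at used promoters in general was therefore not excluded. The core was picked from words that had been tested in part on the same arms, so neither test is independent. Most summits lack the core, and a tie to CG31441 itself was not tested.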
